A study of Mus musculus with 38 samples.

How the data were processed

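Gene expression was measured on 38 arrays, 1 per mouse, with RNA from random pieces of lung labelled with Cy5 and a universal mouse reference RNA, pooled from 11 cell lines, labelled with Cy3. Dose, day, strain, sex and dyes are given by the deposited labels. The authors' scanner files hold, per the file headers, the median intensity of each spot and of its local background in each dye, written by Agilent Feature Extraction 11.0.1.1. The same deposited files hold processed signals, also an intensity per the file headers, after background subtraction, spatial detrending and dye normalization by that program. A deposited series table holds a log2 ratio of Cy5 over Cy3 per probe and array. The authors' method for that table is not stated. Its unit was found from the values, since each of its 38 columns correlated best with its own array, with r from 0.993 to 0.998 across probes and slopes from 0.987 to 0.996. Spot flags for outliers and for signal well above background came from the scanner files.

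Each array holds 62976 spots, of which 3671 are control spots and 59305 carry 55681 distinct probes. The array design refers to the mm9 build. Probe names were taken from the RefSeq accession of each probe through a RefSeq table of GRCm38.p6, which was used for gene names only. A name was found for 28026 of the 55681 probes, covering 21154 symbols. The others kept their own names. No coordinates were used.

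Log2 ratios were computed from the median signals with limma 3.58.1 in R 4.3.3 and the data.table package, version 1.17.8. The background was corrected by normexp with an offset of 50, and each array was normalised by loess with weight 0 for control spots. The plan named the mean signal of a spot, but the files hold only medians, so the median was used in its place. Control spots and outlier spots were left out, spots of a probe were averaged, and probes well above background in Cy5 on fewer than 4 of the 38 arrays were dropped. This left 32459 probes. For the 5830 genes with more than 1 probe, the probe with the highest mean brightness was kept, giving 24047 genes, of which 15585 have a RefSeq symbol and 113 have a missing value on at least 1 array. The signal behind each value is limited by brightness over background and its precision by the number of arrays.

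Arrays were grouped by dose and day as labelled, giving 8 groups. For 1 array of 162 µg the title states 1 day and the characteristics state 28 days, and it was kept in the day 28 group, as replicate 4. Replicate numbers equal the slide number, except for replicate 4 of day 28 at 54 and 162 µg, which lie on slide 5, so a number marks a shared slide and scan day. A single limma model of 8 group means was fitted over all 38 arrays. Each p uses a spread between mice pooled over all groups, which differ in spread. Tests were two-sided, and p was adjusted by Benjamini-Hochberg within each of 10 contrasts at a threshold of 0.05. A gene past that threshold is called higher or lower. The contrasts were each dose against the controls of its day, the difference of each dose's effect between days, and the controls of day 28 against those of day 1. The arrays lie on 5 slides, each holding up to 1 array of every group, and the slides were scanned on 3 days. Differences within slides are given beside the results, and the fit was repeated with slide as a block.

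A set of 43 gene lists, covering tissue responses and cell or tissue markers, was tested with limma's camera at a preset correlation of 0.01, adjusted over the 43 lists. The alternatives were camera with an estimated correlation and fry, which asks whether the genes of a list move on balance in 1 direction and does not compare the list with other genes. The number of called members is given over all genes tested and adjusted over the list alone. The model, the lists, the contrasts, the rule for named genes and 20 alternative settings were chosen before the data were examined, as were the 38 repeats that each leave out 1 array. For 162 µg against 0 µg at each day, the rule took the 10 largest rises and 6 largest falls among called genes with a proper symbol and the same sign on every slide. It added up to 4 members of each list that passed and 2 of each other list, and for each other contrast 5 rises and 3 falls. For a gene not well above background on any array of a group, the Cy5 level there was raised to the dimmest probe well above background on the same array, and the fold is given as at least the resulting value, or not given where that value exceeds the fold of the ratios.

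A further 4 settings were added after the data were seen, because muscle markers differed between day 1 arrays. These are a skeletal muscle score as a covariate, the score together with slide as a block, leaving out the 7 arrays whose score lay more than 1.5 above the median, and 162 µg against 18 µg at day 1. The score is the mean log2 ratio of the 20 markers of the skeletal muscle list.

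The procedure was tested on simulated data, normal noise with each gene's own spread within groups and 200 of 23934 genes changed. At day 1 and 162 µg it recovered 74.6%, 89.6% and 98.5% of genes changed 1.5-fold, 2-fold and 4-fold, with 9 unchanged genes called. At day 28 and 162 µg it recovered 74.6%, 92.5% and 100%, with 13 unchanged genes called. Only the shifted list of the 43 passed in each, but noise set per gene does not test lists of correlated genes. The effects of doses within a day share their controls.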

Results

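The series examined how the mouse lung responds, at the level of transcripts, to titanium dioxide nanoparticles placed once in the trachea. Female C57BL/6 mice received 0, 18, 54 or 162 µg of particles labelled DQ TiO2, a name the labels do not spell out, and lungs were taken after 1 or 28 days. Each of the 38 arrays measured 1 mouse. The day 1 groups hold 5 mice each, as do the day 28 groups at 0 and 18 µg, and the day 28 groups at 54 and 162 µg hold 4 mice each. Between 43.2% and 56.2% of probes were well above background in the sample dye, with a median of 51.2%. The group means ranged from 50.2% ± 4.02 (SD, n = 5) in day 28 controls to 53.5% ± 2.16 (SD, n = 4) at day 28 and 162 µg.

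Markers of tissue that adjoins the lung differed between arrays. The mean log2 ratio of 20 skeletal muscle markers (± SD, n = 5) was 3.72 ± 2.28 in day 1 controls and -0.28 ± 0.14 at 18 µg. It was 2.08 ± 2.94 at 54 µg and 0.69 ± 1.91 at 162 µg of day 1. High scores, from 3.59 to 5.56, were found on 7 arrays, namely replicates 2, 3, 4 and 5 of the day 1 controls, replicates 2 and 5 of 54 µg and replicate 1 of 162 µg. The highest score of the other 31 arrays was 1.06, and all day 28 group means lay between -0.17 and 0.16. Markers of the upper airway, oesophagus and thyroid averaged 1.09 in day 1 controls, with arrays from -0.13 to 2.73 (n = 5). The first principal component of all genes held 37.4% of the variance, and its absolute correlation with the muscle score was 0.951 over arrays that fall into separate clusters.

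**Figure D1:**
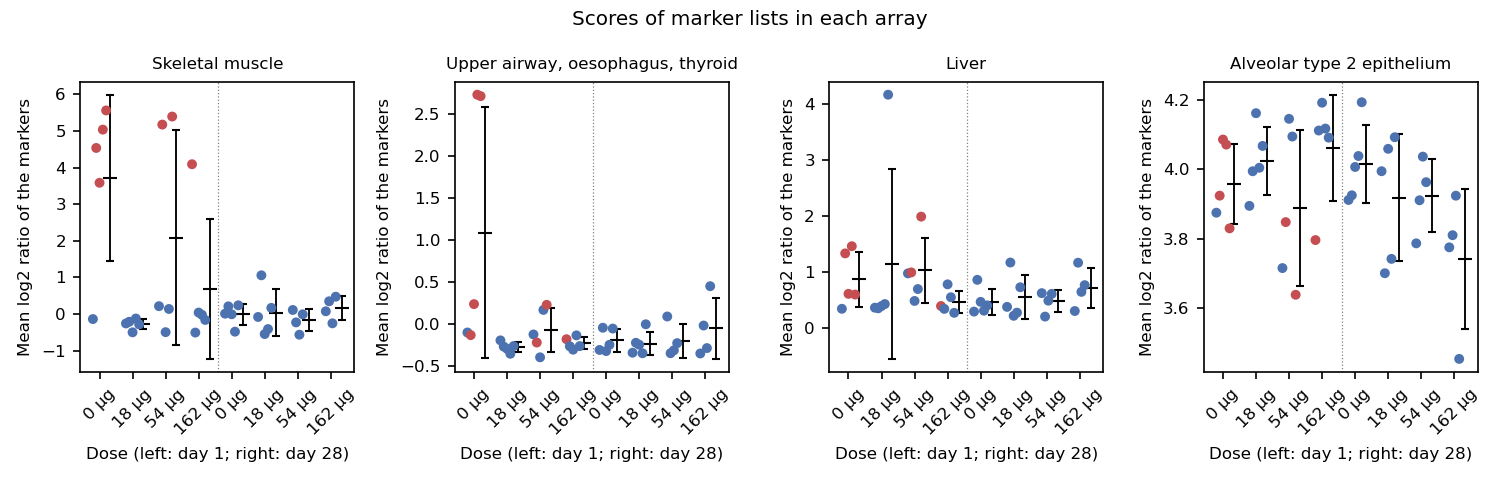
Mean log2 ratio (Cy5 sample over Cy3 reference) of the markers of each tissue list on the vertical axis, per group of day and dose on the horizontal axis, with 1 point per array and a black bar for mean ± SD. Red points are the 7 arrays with a skeletal muscle score from 3.59 to 5.56, all of them at day 1, and blue points are the other 31 arrays.

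At day 1, lungs given 162 µg were compared with controls to ask which transcripts respond soon after instillation. Saa3, an acute phase serum amyloid A protein, was 13.2-fold higher (log2 3.72, SE 0.54, n = 5 against 5, adjusted p = 0.000182). Cxcl5, a chemokine that attracts neutrophils, was 9.26-fold higher (log2 3.21, SE 0.41, adjusted p = 2.6e-05), with control signal well above background on 2 of 5 arrays. Slc26a4, the anion exchanger pendrin, rose 7.22-fold (log2 2.85, SE 0.43, adjusted p = 0.000256). Lcn2, a lipocalin that binds bacterial siderophores, rose 4.40-fold (log2 2.14, SE 0.22) and had the smallest adjusted p of the comparison, 4.11e-07. Within slides the log2 difference ran from 2.11 to 6.26 for Saa3, 2.31 to 4.41 for Cxcl5, 1.74 to 3.52 for Slc26a4 and 1.54 to 2.72 for Lcn2. A rise on 5 of 5 slides was a condition for naming a gene among the largest rises. The acute phase genes Saa1 (log2 2.40, SE 0.34, 5.28-fold) and Saa2 (log2 1.95, SE 0.29, at least 3.72-fold) rose as well, and no control array had Saa2 well above background. So did Ly6i (log2 2.52, SE 0.32) and Ly6f (log2 2.31, SE 0.30), which encode Ly6 surface proteins, the chemokine Ccl17 (log2 1.84, SE 0.26) and Timp1, an inhibitor of metalloproteinases (log2 1.81, SE 0.27). Their adjusted p lay between 2.6e-05 and 0.000256, and Ly6f was well above background on 3 of 5 control arrays. Each was higher on 5 of 5 slides, as the same condition requires.

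These 10 genes kept their call in each of the 38 fits that leave out 1 array and with slide as a block. With the skeletal muscle score as a covariate they also kept it, at log2 4.59 for Saa3 (adjusted p = 1.47e-05), 3.19 for Cxcl5 (adjusted p = 0.000425) and 2.02 for Lcn2 (adjusted p = 1.47e-05). In a fit of the groups compared alone, 4 of them lost it, Saa3 (adjusted p = 0.097), Saa1 (adjusted p = 0.205), Timp1 (adjusted p = 0.287) and Saa2 (adjusted p = 0.351). Without the 7 arrays of high muscle score, which leaves 1 day 1 control, none of the 10 kept its call.

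**Figure D2:**
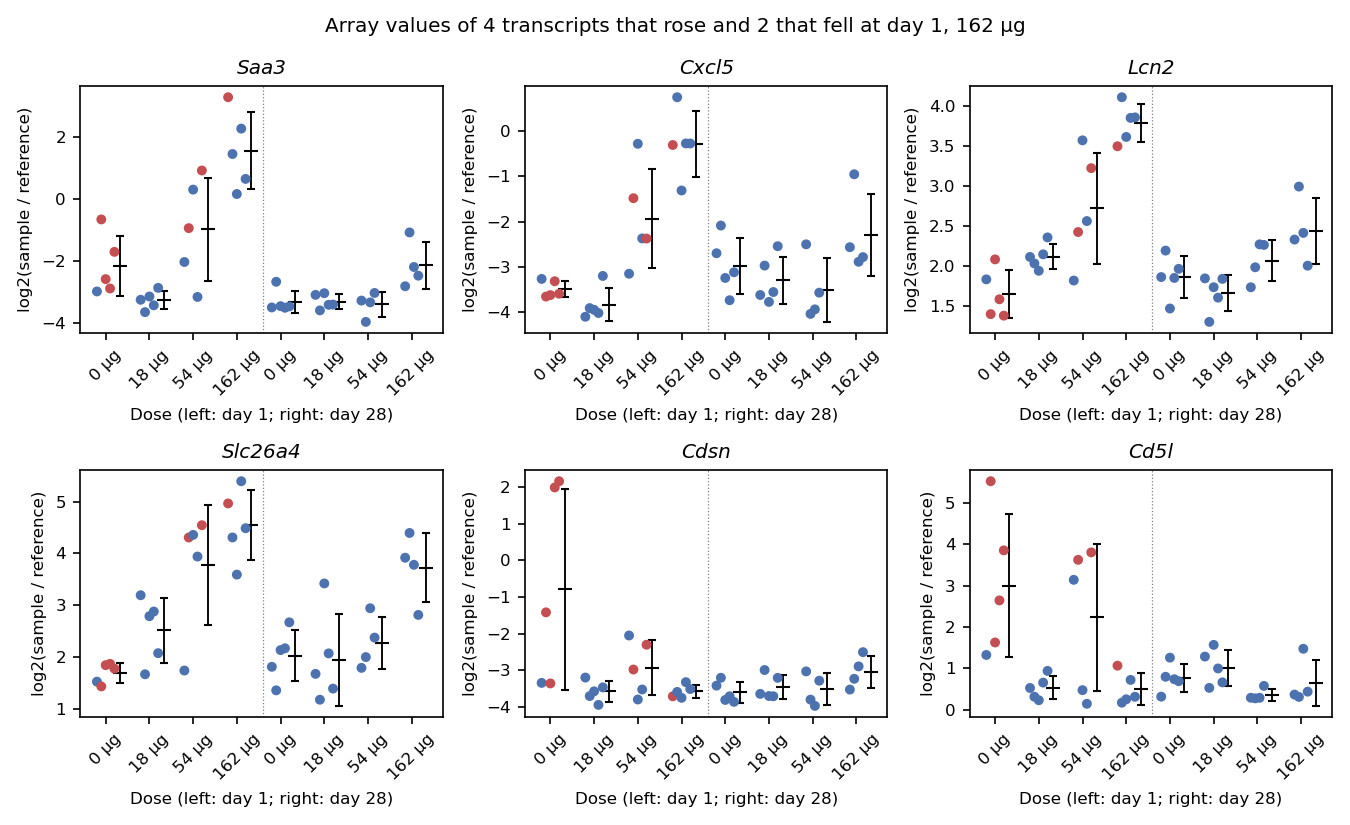
Log2 ratio (Cy5 sample over Cy3 reference) on the vertical axis for genes named in the text, by dose in µg at day 1 and day 28 on the horizontal axis, with 1 point per array and a black bar for mean ± SD. At day 1 the mean of Lcn2 is 1.65 in controls, 2.11 at 18 µg, 2.72 at 54 µg and 3.79 at 162 µg, and red points mark arrays with a high skeletal muscle score.

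Of genes with a symbol lower on every slide, the 6 with the largest falls at day 1 and 162 µg include 2 of cornified epithelium, beside controls with high upper airway and muscle scores. Cdsn, the corneodesmosin of cornified epithelium, fell 6.85-fold (log2 -2.78, SE 0.64, n = 5 against 5, adjusted p = 0.0281) and Sbsn, suprabasin, fell 4.49-fold (log2 -2.17, SE 0.49, adjusted p = 0.0270). Cd5l, a protein secreted by macrophages, fell 5.60-fold (log2 -2.49, SE 0.57, adjusted p = 0.0281) and was well above background on 3 of 5 arrays at 162 µg. Neu2, a sialidase, fell 3.12-fold (log2 -1.64, SE 0.37, adjusted p = 0.0248). The nicotinic receptor subunit gene Chrna9 fell at least 3.08-fold (log2 -1.68, SE 0.38, adjusted p = 0.0251) and the aldehyde dehydrogenase gene Aldh3b2 at least 2.82-fold (log2 -1.67, SE 0.38, adjusted p = 0.0256), with no 162 µg array well above background for either. All 6 were lower on 5 of 5 slides because the rule for named genes requires it. The log2 difference of Cdsn ran from -5.66 to -0.37 between slides and that of Cd5l from -5.34 to -0.26. Group means of Cdsn (± SD, n = 5) were -0.79 ± 2.73 in controls, -3.57 ± 0.28 at 18 µg and -3.57 ± 0.17 at 162 µg. Its SE pools these unequal spreads.

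None of the 6 kept its call with the muscle score as a covariate, where Cdsn had log2 -1.81 (adjusted p = 0.581), Cd5l -1.34 (adjusted p = 0.632), and Sbsn -1.60 (adjusted p = 0.466). Neu2 had log2 -1.16 (adjusted p = 0.478), Chrna9 -1.24 (adjusted p = 0.461) and Aldh3b2 -1.06 (adjusted p = 0.561). Leaving out control replicate 4 or 5, or replicate 2, 3 or 4 of 162 µg, ended all 6 calls. Leaving out replicate 5 of 162 µg ended them except for Chrna9, replicate 1 of 162 µg ended that of Cdsn, and control replicate 2 that of Cd5l. All 6 calls also ended with median centring and with the compared groups alone, and those of Cd5l and Aldh3b2 with Agilent's processed signals. The highest adjusted p without 1 array was 0.182 for Cdsn, 0.149 for Cd5l, 0.156 for Sbsn, 0.150 for Neu2, 0.152 for Chrna9 and 0.156 for Aldh3b2.

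Acute phase proteins formed the list with the largest called share at day 1 and 162 µg. Of 21 measured members 8 rose and none fell, 10 rose adjusted over the list alone, and the median log2 fold change was 0.62 with 16 members positive and all 5 slides positive (0.21 to 1.04). Camera gave an adjusted p of 7.2e-12, and this was the 1 list that also passed with an estimated correlation (adjusted p = 0.0199 with an estimated correlation, and 0.0418 with slide as a block). Among CXC chemokines, which draw neutrophils and other leukocytes, 1 of 12 rose, Cxcl5, and 5 rose and 1 fell adjusted over the list alone (median 0.42, adjusted p = 0.00257, 5 of 5 slides). The list did not pass with an estimated correlation (adjusted p = 0.117 with an estimated correlation). Cxcl1, given no fold because no control array was well above background, did not pass (adjusted p = 0.0528) but did with slide as a block (adjusted p = 0.0173). Of 16 CC chemokines, which attract monocytes and T cells, Ccl17 rose and 5 rose adjusted over the list alone (median 0.32, adjusted p = 0.000691, 4 of 5 slides), with an adjusted p = 0.188 with an estimated correlation. Skeletal muscle markers moved with each of these lists, being 3.09 lower in median, and with the muscle score as a covariate the medians were 0.83, 0.25 and 0.54, each list then passing with an estimated correlation (adjusted p = 0.000229, 0.0241 and 0.0191 with an estimated correlation).

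Genes of the unfolded protein response, which serve protein folding in the endoplasmic reticulum, were also higher. The chaperone Dnajb11 (log2 0.39, SE 0.07, adjusted p = 0.00242) and the disulfide isomerase Pdia6 (log2 0.50, SE 0.11, adjusted p = 0.0274) were the 2 of 22 members that rose, and 4 rose adjusted over the list alone. The median was 0.22 on 5 of 5 slides (adjusted p = 8.8e-05, and 0.171 with an estimated correlation). Of 17 glucocorticoid targets Lcn2 rose, 2 rose adjusted over the list alone, and the median was 0.40 (adjusted p = 0.000789, and 0.223 with an estimated correlation). No member of 30 actin cytoskeleton genes rose, 3 did adjusted over the list alone, and the median was 0.17 (adjusted p = 1.12e-05, and 0.226 with an estimated correlation). The neutrophil list had 0 of 28 members called, with 5 higher and 1 lower adjusted over the list alone, and a median of 0.12 on 5 of 5 slides (adjusted p = 0.0364, and 0.482 with an estimated correlation). Retnlg, a resistin-like gene of neutrophils, had log2 1.29 (SE 0.33, adjusted p = 0.0571) and passed with slide as a block (adjusted p = 0.0158). Pdia6 lost its call without control replicate 4 or 5 or without replicate 1, 2, 3 or 4 of 162 µg (adjusted p up to 0.177). Dnajb11 and Pdia6 lost theirs with median centring, the compared groups alone and without the 7 arrays of high muscle score, and Pdia6 also with the array of conflicting labels placed in day 1 and with the muscle score as a covariate (adjusted p = 0.411). Skeletal muscle markers moved with these 4 lists. The covariate gave glucocorticoid targets a median of 0.024 and ended the calls of actin (median 0.039, adjusted p = 0.223) and neutrophils (median 0.12, adjusted p = 0.0558). Actin had a median of 0.030 without the 7 arrays.

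**Figure D3:**
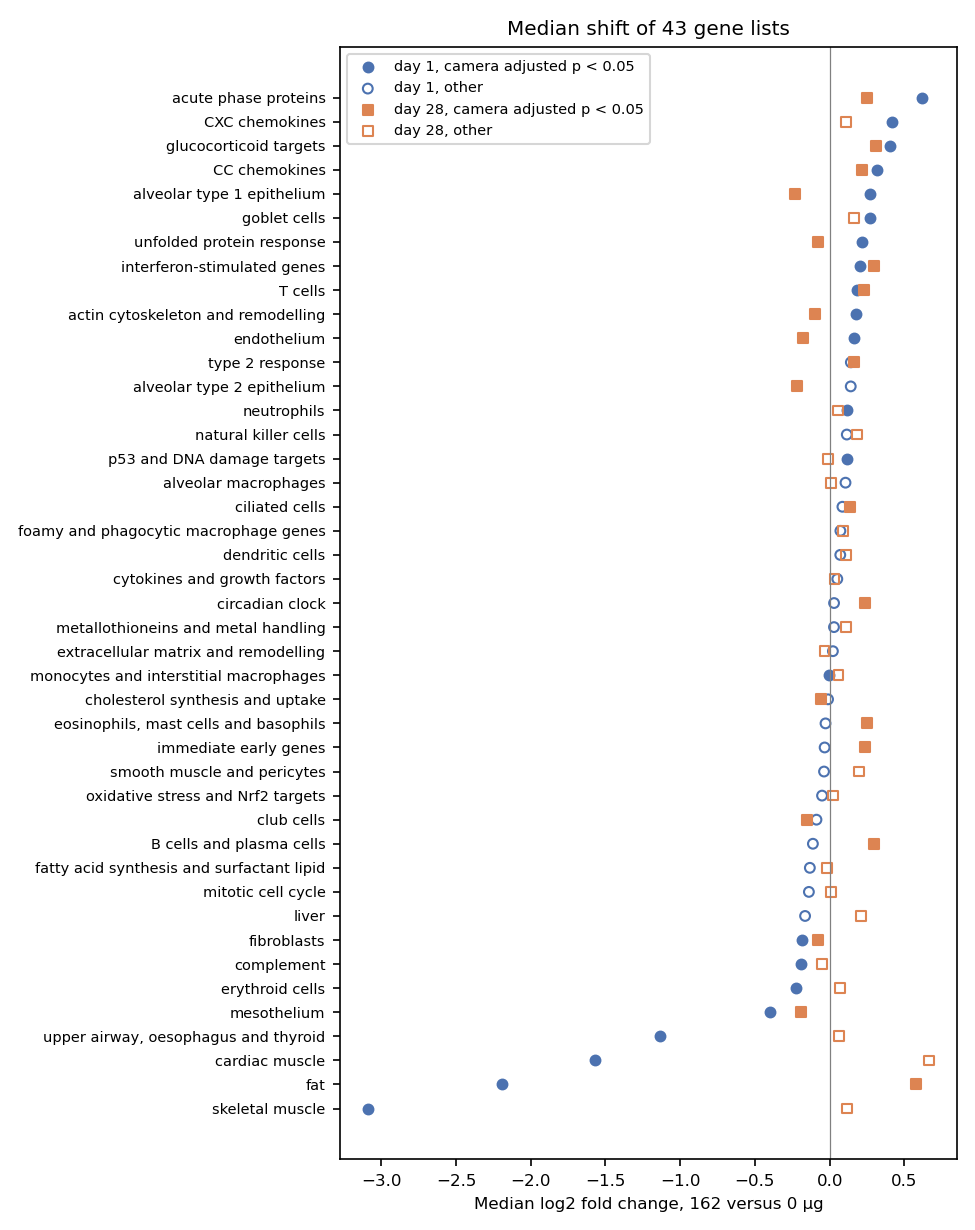
Median log2 fold change of each of the 43 gene lists for 162 µg against 0 µg at day 1 and day 28, with the lists on the vertical axis and the median on the horizontal axis. Filled points have a camera adjusted p under the threshold, 22 lists at day 1 and 21 at day 28, and the median of the acute phase list is 0.62 at day 1 and 0.25 at day 28.

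The lists with the lowest medians at day 1 and 162 µg were those of neighbouring tissue, which were high in the controls. Skeletal muscle markers had a median of -3.09 over 20 members, none called and 16 lower adjusted over the list alone (adjusted p = 1.94e-14, and 0.188 with an estimated correlation), and slide medians ran from -6.22 to 4.47. Acta1, the actin of skeletal muscle, had log2 -5.42 (SE 1.55, adjusted p = 0.0971). Fat had a median of -2.19 (adjusted p = 6.63e-07, and 0.361 with an estimated correlation). It and cardiac muscle (median -1.57, adjusted p = 1.3e-05, and 0.482 with an estimated correlation) had no called member, also adjusted over the list alone. In the upper airway, oesophagus and thyroid list, 2 of 14 members fell, and 1 rose and 7 fell adjusted over the list alone (median -1.14, adjusted p = 0.000137, and 0.188 with an estimated correlation). These 2 were the squamous keratins Krt4 (adjusted p = 0.0335), given no fold because no 162 µg array was well above background, and Krt14 (log2 -2.04, adjusted p = 0.0495). Both lost their call with the muscle score as a covariate (adjusted p = 0.620 and 0.658) and in 5 and 8 of the planned settings. Krt4 was lower on 3 of 4 slides and lost its call without control replicate 4 or 5 or any of the 5 replicates of 162 µg (adjusted p up to 0.287). Krt14 kept its call only without control replicate 1, 2 or 3 or replicate 3 or 5 of 54 µg, and the adjusted p rose to 0.255 otherwise. The mesothelium (median -0.40, adjusted p = 0.00011, and 0.188 with an estimated correlation), fibroblast (median -0.19, adjusted p = 0.000723, and 0.217 with an estimated correlation) and erythroid (median -0.23, adjusted p = 0.017, and 0.482 with an estimated correlation) lists were lower too, with no called member and 9 fibroblast genes lower adjusted over the list alone. With the muscle score as a covariate fat (median -0.41, adjusted p = 0.223) was not called, nor by construction was skeletal muscle (-0.11, 0.723). Cardiac muscle, mesothelium and upper airway then had 0.40, -0.18 and -0.65.

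Complement genes (median -0.19, adjusted p = 0.0429, and 0.536 with an estimated correlation) had 5 members lower adjusted over the list alone and none called. In the monocyte and interstitial macrophage list 2 of 23 fell, F13a1 (log2 -1.06, SE 0.24, adjusted p = 0.0277) and Folr2 (log2 -1.55, SE 0.36, adjusted p = 0.0312), each lower on 4 of 5 slides, and 5 fell adjusted over the list alone. The median of that list was -0.00 and its mean -0.21 (adjusted p = 0.0278, and 0.466 with an estimated correlation). Both genes lost their call without control replicate 2, 4 or 5 or without replicate 2, 4 or 5 of 162 µg, and F13a1 also without replicate 3 (adjusted p up to 0.166 and 0.139). They also lost it with the muscle score as a covariate (log2 -0.54 and -0.66, adjusted p = 0.632 and 0.658), median centring and the compared groups alone. Higher medians were found for interferon-stimulated genes (0.20, adjusted p = 2.59e-05, and 0.466 with an estimated correlation), alveolar type 1 epithelium (0.27, adjusted p = 0.00305), T cells (0.18, adjusted p = 0.00305) and endothelium (0.16, adjusted p = 0.00488), the last 3 at 0.482 with an estimated correlation. Goblet cell markers had a median of 0.27 (adjusted p = 0.0429, and 0.583 with an estimated correlation) and p53 targets one of 0.11 (adjusted p = 0.0468, and 0.449 with an estimated correlation). Among these 6 lists the called members were 1 of type 1 epithelium, Pdpn, a membrane protein of those cells (log2 0.90, SE 0.19, adjusted p = 0.016), and 1 of goblet cells, Slc26a4. Adjusted over the list alone there were 3 p53 targets and 1 in each of the lists of type 1 epithelium and goblet cells. Pdpn lost its call without control replicate 4 or 5 or replicate 2 or 4 of 162 µg (adjusted p up to 0.0954). Skeletal muscle markers moved with all of these lists, and with the muscle score as a covariate complement (median -0.043), T cells (0.027, adjusted p = 0.842), endothelium (-0.039, 0.868) and p53 targets (-0.018, 0.704) were not called. Type 1 epithelium then had -0.16, interferon-stimulated genes 0.095, monocytes -0.12 and goblet cells 1.08.

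Several of these list calls rest on single arrays. Leaving out control replicate 2 ended 6, complement (adjusted p = 0.866), p53 targets (0.186), neutrophils (0.0747), monocytes (0.266), goblet cells (0.164) and erythroid cells (0.0779). Replicate 2 of 162 µg ended complement, p53, neutrophils and monocytes (0.0645 to 0.105), replicate 3 ended p53, glucocorticoid targets, neutrophils, goblet cells and endothelium (0.0531 to 0.124), and replicate 5 ended complement, T cells and erythroid cells (0.0557 to 0.0915). Control replicate 1 ended neutrophils (0.312) and goblet cells (0.409), replicate 4 of 162 µg goblet cells (0.447) and replicate 1 of 162 µg erythroid cells (0.205). The p53 list also lost its call without control replicate 3 (0.0746), replicate 4 of 54 µg (0.0507), replicate 2 of day 28 controls (0.0508) or replicate 1 of day 28 and 54 µg (0.05). Medians that 1 array moved by over 1.5 times while the call held were CXC chemokines (0.22 without replicate 4 of 162 µg), cardiac muscle (-0.94 without replicate 2), upper airway (-0.74 without control replicate 4), mesothelium (-0.23 without control replicate 2) and fibroblasts (-0.11 without control replicate 2 and -0.12 without replicate 2 of 162 µg). Endothelium was 0.10 without control replicate 5 and 0.29 without replicate 1 of 162 µg, goblet cells 0.43 without control replicate 3 and 0.52 without replicate 2 of 162 µg, and neutrophils 0.20 and 0.18 without replicates 1 and 5 of 162 µg. Where the call ended as well, complement was -0.087, erythroid cells -0.13 without control replicate 2 and -0.054 without replicate 1 of 162 µg, glucocorticoid targets 0.17, endothelium 0.10 and p53 targets 0.057 without replicate 3, and goblet cells 0.15 without control replicate 1 and 0.077 without replicate 4. The monocyte median lay between -0.092 and 0.019 over these fits.

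Planned settings also ended such calls. Fry passed 10 of the 22 lists, acute phase proteins, CXC and CC chemokines, actin, the unfolded protein response, glucocorticoid targets, fibroblasts, mesothelium, skeletal muscle and upper airway. Agilent's processed signals ended complement, p53, neutrophils, monocytes, type 1 epithelium, goblet cells and endothelium (adjusted p from 0.0545 to 0.292). Array weights ended complement, p53, neutrophils, monocytes, goblet and erythroid cells (0.0712 to 0.390), and scale normalization complement, p53, monocytes and erythroid cells (0.122 to 0.412). No background correction and the compared groups alone each ended complement, p53 and monocytes (0.0636 to 0.0833), and the series table complement, p53 and goblet cells (0.0579 to 0.0939). Median centring ended complement (0.0824), Cy5 alone p53 (0.0523), the filter of 19 arrays p53 (0.0639) and goblet cells (0.0517), and placing the array of conflicting labels in day 1 p53 (0.0742) and neutrophils (0.110). Without the 7 arrays of high muscle score 7 of the 22 lists kept their call, acute phase proteins, CXC and CC chemokines, the unfolded protein response, neutrophils, goblet cells and endothelium.

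Of the remaining 21 lists at day 1 and 162 µg, none passed camera. In the oxidative stress list of Nrf2 targets 1 of 28 rose and 1 fell, or 2 and 2 adjusted over the list alone (median -0.05, adjusted p = 0.512), and the glutathione synthesis gene Gclc was the one that rose (log2 0.77, SE 0.16, adjusted p = 0.0159). The cytokine list (median 0.05, adjusted p = 0.16, 3 higher and 1 lower adjusted over the list alone) held 1 riser, Csf2, a growth factor of granulocytes and macrophages (log2 0.94, SE 0.18, adjusted p = 0.0063, 5 of 5 slides). Alveolar macrophage markers had 2 of 25 called (4 higher and 1 lower adjusted over the list alone), the integrin gene Itgax (log2 0.58, adjusted p = 0.0248) and the carbonic anhydrase gene Car4 (log2 0.75, adjusted p = 0.0162). The median of that list was 0.11 (adjusted p = 0.0621, 0.0478 with slide as a block, and 0.513 with that block and an estimated correlation). Alveolar type 2 epithelium had none of 24 called, 1 higher adjusted over the list alone, and a median of 0.14 (adjusted p = 0.0644, 0.0478 with slide as a block, and 0.530 with that block and an estimated correlation). The type 2 response (median 0.14, adjusted p = 0.175) and the eosinophil, mast cell and basophil list (median -0.03, adjusted p = 0.11) had 1 riser and 1 faller each. Adjusted over the list alone there were 2 and 1 in the former and 1 and 5 in the latter. The faller in both was the lipoxygenase gene Alox15 (log2 -1.63, SE 0.38, adjusted p = 0.0281). A single member rose in each of the extracellular matrix (median 0.02, adjusted p = 0.116), mitotic (median -0.14, adjusted p = 0.133) and dendritic cell (median 0.07, adjusted p = 0.144) lists, and 2 in the foamy macrophage list (median 0.07, adjusted p = 0.303). Adjusted over the list alone there were 5, 4 and 2 risers, and 4 risers and 1 faller. The fatty acid (median -0.13), B cell (-0.11), liver (-0.16), natural killer cell (0.11), metallothionein (0.03), circadian (0.03), immediate early (-0.03), club cell (-0.09), ciliated cell (0.09), smooth muscle (-0.04) and cholesterol (-0.01, mean 0.02) lists had no called member and adjusted p between 0.116 and 0.893, and adjusted over the list alone 2 metallothionein genes and 1 liver gene were higher. With the muscle score as a covariate Csf2 (adjusted p = 0.173), Gclc (0.429), Itgax (0.608), Car4 (0.425), Pdpn (0.466) and Alox15 (0.632) were not called. Median centring ended these 6 calls too, and the compared groups alone all but that of Csf2. Gclc lost its call without control replicate 5 or replicate 2 of 162 µg (up to 0.0762). Car4 lost it without control replicate 4 or 5 or replicate 4 of 162 µg (up to 0.0947). Itgax and Alox15 lost theirs without control replicate 2, 4 or 5 or replicate 2, 3, 4 or 5 of 162 µg (up to 0.137 and 0.182).

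Over all 24047 genes, 150 were called at day 1 and 162 µg, 86 higher and 64 lower, and 100 of them changed at least 1.5-fold. At an unadjusted p under 0.05 there were 3576 genes, where 1202 would fall by chance. The count was 349 (178 higher and 171 lower) with slide as a block, and all 150 genes were among them. With the muscle score as a covariate it was 23, all higher, of which 18 were among the 150, and the 86 higher genes had a median of 0.49 (0.63 without it) and the 64 lower genes -0.55 (-0.97). Without the 7 arrays of high muscle score the count was 1. It was 19 (13 higher and 6 lower) with median centring, 12 with the compared groups alone, 215 (151 higher and 64 lower) in the series table, 1705 with array weights and 94 with the array of conflicting labels placed in day 1. Single arrays moved it too, to 1337 without control replicate 1, 287 without control replicate 2, 435 without control replicate 3, 38 without control replicate 4 and 30 without control replicate 5. It was 50, 96 and 46 without replicates 2, 3 and 4 of 162 µg and 228 without replicate 5 of 54 µg.

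At the lower doses of day 1 the genes raised at 162 µg were followed by dose. The mean log2 ratio of Slc26a4 was 1.69 ± 0.20 (SD, n = 5) in controls, 2.52 ± 0.63 (SD, n = 5) at 18 µg, 3.78 ± 1.16 (SD, n = 5) at 54 µg and 4.55 ± 0.68 (SD, n = 5) at 162 µg. Against controls at 54 µg, Slc26a4 had log2 2.08 (adjusted p = 0.0977), Lcn2 1.07 (adjusted p = 0.0977), Cxcl5 1.56 (adjusted p = 0.206) and Saa3 1.18 (adjusted p = 0.506). At 18 µg Lcn2 had log2 0.46 (adjusted p = 0.27) and Saa3 -1.10 (adjusted p = 0.298).

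At 18 µg and day 1, limma called 1 gene, higher and without a symbol, and at 54 µg it called 0 genes, with 4013 and 2201 genes at an unadjusted p under 0.05. With slide as a fixed block the counts were 437 (93 higher and 344 lower) and 4, and with slide as a random block 362 and 0. They were 3 and 259 (230 higher and 29 lower) with the muscle score as a covariate, 3 and 249 with slide as well, and with array weights 2100 and 385. Skeletal muscle markers were lower at 18 µg (median -3.88, 19 of 20 lower adjusted over the list alone, 5 of 5 slides, adjusted p = 6.92e-22, and 0.34 with an estimated correlation) and at 54 µg (median -1.78, 3 of 5 slides, adjusted p = 8.12e-06, and 0.71 with an estimated correlation). At 18 µg the median was 0.21 for the actin cytoskeleton (5 higher adjusted over the list alone, adjusted p = 4.42e-05, and 0.41 with an estimated correlation) and 0.31 for T cells (6 higher, adjusted p = 4.83e-05, and 0.499 with an estimated correlation). It was 0.34 for the circadian clock (6 higher and 3 lower, adjusted p = 0.0219, and 0.41 with an estimated correlation), whose call ended without control replicate 2 (adjusted p = 0.051), control replicate 3 (0.0612) or replicate 5 of 18 µg (0.0565) and in the series table (0.0622). With the muscle score as a covariate the calls at 18 µg ended for actin (median -0.035, adjusted p = 0.930), T cells (0.023, 0.444) and the clock (0.070, 0.450). That of skeletal muscle (-0.017, 0.966) ended by construction. At 54 µg it was 0.47 for goblet cells (4 higher adjusted over the list alone, 4 of 5 slides, adjusted p = 8.48e-06) and 0.24 for T cells (adjusted p = 8.48e-06), both at 0.514 with an estimated correlation. The acute phase list had 0.27 at 54 µg (1 higher adjusted over the list alone, 2 of 5 slides, adjusted p = 0.00792, and 0.514 with an estimated correlation), and not without control replicate 1 (0.0963) or replicate 5 of 54 µg (0.0757). Array weights ended the calls of goblet cells (median 0.21, adjusted p = 0.0918) and acute phase proteins (0.18, 0.0638), and that of T cells ended without the 7 arrays (0.047, 0.271). The covariate gave T cells 0.11, goblet cells 0.90 and, by construction, skeletal muscle 0.0093 (adjusted p = 0.832). Without replicate 2 of 54 µg the acute phase median was 0.16, and without replicate 3 that of T cells was 0.16, of skeletal muscle -1.03 and of goblet cells 0.86. Goblet cells had 0.31 without control replicate 1 or 2 and 0.73 without control replicate 3, and skeletal muscle -2.75 without control replicate 1. No member of these lists was called over all genes. Camera passed 15 of 43 lists at each of these doses, none with an estimated correlation, and fry passed 3 at 18 µg and 0 at 54 µg.

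Both counts rest on single arrays. The count at 18 µg was 1697, 280 and 482 without control replicates 1, 2 and 3 and 0 without control replicate 4 or 5 or without replicate 2, 4 or 5 of 18 µg. It was 99, 80, 48 and 454 without replicates 2, 3, 4 and 5 of 54 µg, 56 without replicate 1 of 162 µg, 7 without replicate 4 of day 28 and 162 µg, and 13 and 4 without replicates 1 and 2 of day 28 and 18 µg. The count at 54 µg was 241, 251 and 9 without control replicates 1, 2 and 3 and 3 without replicate 1 of 54 µg.

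Because the 18 µg group of day 1 had the lowest muscle scores, 162 µg was also compared with 18 µg, a comparison chosen after the data were seen. Cxcl5 was higher by log2 3.56 (adjusted p = 4.08e-06), Timp1 by 1.83 (adjusted p = 0.000304) and Ccl17 by 1.35 (adjusted p = 0.0231), each with n = 5 against 5. Saa3 was higher by 4.83 (adjusted p = 2.97e-06) and Lcn2 by 1.67 (adjusted p = 3.3e-05), while Cdsn differed by 0.00 and Slc26a4, at log2 2.02, was not called (adjusted p = 0.0593). In all 13 genes were called, 12 higher and 1 lower, against 986 at an unadjusted p under 0.05, and the 12 were among the 86 above, for which the same 162 µg arrays were used. With slide as a block 18 were called, and none of the 64 lower genes was among the 13. Lists that passed with an estimated correlation were acute phase proteins (median 0.53, adjusted p = 0.000139), CXC chemokines (0.29, 0.000219), CC chemokines (0.38, 0.00527), the unfolded protein response (0.22, 0.000532) and glucocorticoid targets (0.35, 0.0355). Skeletal muscle markers had a median of 0.95 in this comparison (adjusted p = 0.637 with an estimated correlation).

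At day 28, lungs given 162 µg were compared with controls to ask which transcripts still differ. No single gene passed. Surfactant genes of alveolar type 2 epithelium had lower values, with Sftpc at log2 -1.04 (SE 0.34, n = 4 against 5, adjusted p = 0.62), Sftpb at -0.84 (SE 0.26) and Sftpa1 at -0.72 (SE 0.22). The club cell genes Cyp2f2, a cytochrome, and Scgb1a1, the main secretory protein of those cells, had log2 -1.04 (SE 0.28) and -0.78 (SE 0.23). The interferon-induced genes Oas1a and Irf7 had log2 0.71 (SE 0.22) and 0.68 (SE 0.24). Without replicate 4 of 162 µg, the array with conflicting day labels, Sftpc was at -0.68, Sftpb at -0.56, Sftpa1 at -0.52, Cyp2f2 at -0.72 and Scgb1a1 at -0.44. Without replicate 2 of 162 µg Oas1a was at 0.31 and Irf7 at 0.22. Limma called 0 of 24047 genes (smallest adjusted p 0.326), with 1637 at an unadjusted p under 0.05, 0 with slide as a block, 0 with array weights, 2 with the compared groups alone and 3 from Agilent's processed signals. Leaving out replicate 1 of 162 µg gave 3 genes.

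As groups, 21 of 43 lists passed camera at day 28 and 162 µg, 12 higher and 9 lower, but none with an estimated correlation and none by fry. Alveolar type 2 epithelium was lower (median -0.22, 4 of 4 slides, 5 of 24 lower adjusted over the list alone, adjusted p = 7.7e-07), as was type 1 epithelium (median -0.23, 4 of 4 slides, 2 lower, adjusted p = 6.54e-05). Endothelium (median -0.18, 2 lower, adjusted p = 0.000454) and mesothelium (median -0.19, 1 lower, adjusted p = 0.00285) were lower too. Interferon-stimulated genes were higher (median 0.30, 28 of 29 positive, 4 of 4 slides, none past the threshold adjusted over the list alone, adjusted p = 1.17e-10). So were T cells (median 0.23, 3 of 22 higher, adjusted p = 7.7e-07), B cells (median 0.29, 1 higher, adjusted p = 7.41e-05) and immediate early genes (median 0.24, 3 higher, adjusted p = 0.000454). For each of these 8 lists the adjusted p was 0.436 with an estimated correlation. Club cells had a median of -0.15 (3 lower, adjusted p = 0.00314, and 0.484 with an estimated correlation). The calls of type 2 epithelium (adjusted p = 0.412), type 1 epithelium (0.155), club cells (0.562) and endothelium (0.571) ended in the Cy5 channel alone, and that of B cells (0.0808) with Agilent's processed signals. No array left out ended any of these 9, but single 162 µg arrays carry part of several medians. Without replicate 2 the interferon median was 0.087 (adjusted p = 0.0329), mesothelium -0.053 and endothelium -0.085. Without replicate 4 endothelium was -0.12, without replicate 3 immediate early genes 0.15 and club cells -0.097, and club cells were -0.040 without replicate 1 and -0.098 without control replicate 3.

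A further 12 lists passed with larger p. Acute phase proteins had a median of 0.25 with 18 of 21 positive (adjusted p = 0.0107), eosinophils, mast cells and basophils 0.25 (1 higher adjusted over the list alone, 0.025), the unfolded protein response -0.08 (1 higher and 3 lower, 0.0252), and the type 2 response 0.17 (0.0267), all at 0.436 with an estimated correlation. Glucocorticoid targets had 0.31 (0.0275), fibroblasts -0.08 (0.0296), the circadian clock 0.24 (3 higher, 0.0304) and CC chemokines 0.22 (0.0304), all at 0.436 with an estimated correlation. Cholesterol synthesis (median -0.06, 0.025, and an adjusted p = 0.576 with an estimated correlation), actin (-0.10, 0.0289, and 0.595), ciliated cells (0.14, 0.0377, and 0.870) and fat (0.58, 2 of 4 slides, 0.00342, and 0.595) completed them. With slide as a block the calls of CC chemokines (0.128), glucocorticoid targets (0.0724) and the circadian clock (0.0549) ended. Agilent's processed signals ended 9 of the 12 (0.0637 to 0.348), and median centring (0.0672 to 0.839) and Cy5 alone (0.145 to 0.731) those of cholesterol synthesis, actin, fibroblasts and the unfolded protein response. Each of these 12 calls was ended by at least 1 array left out, and replicate 4 of 162 µg, whose day labels conflict, ended 9 (adjusted p from 0.0527 to 0.317). Among 162 µg arrays replicate 2 ended 7 (0.0963 to 0.825), including the acute phase list (0.104), replicate 3 ended 4 (0.0575 to 0.136) and replicate 1 ended 1 (0.112). Control replicates 1 to 5 ended 4 (0.0547 to 0.104), 2 (0.0506 to 0.0785), 8 (0.0629 to 0.135), 4 (0.0693 to 0.127) and 3 (0.0585 to 0.143). Medians also moved by over 1.5 times. Without control replicates, fat was 1.01 (replicate 2), the type 2 response 0.26 and 0.31 (3 and 5), cholesterol synthesis -0.10, -0.026 and -0.089 (1, 2 and 5), the unfolded protein response -0.046 and -0.048 (3 and 5), the circadian clock 0.12 (5) and fibroblasts -0.028 (5). Without replicate 1 of 162 µg the type 2 response was 0.26, ciliated cells 0.32 and fibroblasts -0.040. Without replicate 2 acute phase proteins were 0.14, CC chemokines 0.080, the type 2 response 0.085, cholesterol synthesis -0.11, ciliated cells 0.059 and fibroblasts -0.036. Without replicate 3 the type 2 response was 0.33, the circadian clock 0.095, glucocorticoid targets 0.18, ciliated cells 0.20 and fibroblasts -0.12. Without replicate 4 actin was -0.054, glucocorticoid targets 0.21 and ciliated cells 0.090.

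The other 22 lists did not pass at day 28 and 162 µg. The largest medians among them were those of cardiac muscle (0.66, adjusted p = 0.19), liver (0.21, adjusted p = 0.548) and smooth muscle (0.20, adjusted p = 0.0957). Natural killer cells had 0.18 (adjusted p = 0.102) and goblet cells 0.16 (1 higher adjusted over the list alone, adjusted p = 0.196). Foamy macrophage genes had 0.09 (2 higher adjusted over the list alone, adjusted p = 0.148). Neutrophils (median 0.05), CXC chemokines (0.11), metallothioneins (0.11), dendritic cells (0.11), skeletal muscle (0.12), upper airway (0.06), monocytes (0.06), the mitotic cycle (0.01), complement (-0.05) and extracellular matrix (-0.03) had adjusted p between 0.346 and 0.972. Erythroid cells (median 0.07, mean -0.09, 2 lower adjusted over the list alone), fatty acid synthesis (median -0.02, mean 0.05), p53 targets (median -0.01, mean 0.05), cytokines (median 0.03, mean -0.00), alveolar macrophages (median 0.01) and Nrf2 targets (median 0.02) had a median and a mean, or a median and a camera direction, of opposite sign, with adjusted p between 0.221 and 0.998. The genes raised at day 1 had values above controls, with Slc26a4 at log2 1.69 (adjusted p = 0.62), Ly6i at 1.72 (adjusted p = 0.326) and Saa3 at 1.18 (adjusted p = 0.73). Of the 86 genes 65 had a positive value, with a median of 0.13, and no gene was called on both days.

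At day 28 and 18 µg, 20 genes were called, 14 higher and 6 lower, against 2049 at an unadjusted p under 0.05, and 6 of the 20 have a symbol. Has1, a hyaluronan synthase, rose 2.51-fold (log2 1.33, SE 0.25, n = 5 against 5, adjusted p = 0.00833), and Wdr92 (log2 1.31, adjusted p = 8.25e-05) and the methyl-CpG binding gene Mbd1 (log2 1.00, adjusted p = 0.000209) rose as well. Fkbp2, a peptidyl-prolyl isomerase (log2 -0.90, adjusted p = 0.00833), Ykt6, a SNARE protein (log2 -0.46, adjusted p = 0.0335), and Rcn1, a calcium-binding protein of the endoplasmic reticulum (log2 -0.36, adjusted p = 0.0312), fell. Each gene moved the same way on 5 of 5 slides, as the rule for named genes requires. Immediate early genes (median 0.43, 10 higher and 1 lower of 25 adjusted over the list alone, adjusted p = 4.06e-07, and 0.292 with an estimated correlation) and glucocorticoid targets (median 0.56, 7 of 17 higher, adjusted p = 5.41e-07, and 0.167 with an estimated correlation) were higher. The unfolded protein response was lower (median -0.19, 1 higher and 3 lower, adjusted p = 0.000776, and 0.292 with an estimated correlation). The list calls held in each fit without 1 array, with immediate early medians of 0.27 without control replicate 2, 0.28 without replicate 2 and 0.20 without replicate 3 of 18 µg, while 7 lists passed camera and none with an estimated correlation or fry. The count was 45 (22 higher and 23 lower) with slide as a block, 0 with median centring, 7 with the compared groups alone, and 52 without replicate 4 of 18 µg. Mbd1 was not called with the mean of its probes (log2 0.43, adjusted p = 0.104). Has1 lost its call without control replicate 2 (adjusted p = 0.059) and Fkbp2 without replicate 2 or 3 of 18 µg (up to 0.0527). Ykt6 lost it without control replicate 1, 2, 3 or 4 or replicate 2, 3 or 5 of 18 µg (up to 0.150), and Rcn1 without control replicate 1, 2, 3 or 5 or replicate 1, 2, 3 or 5 of 18 µg (up to 0.169).

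At day 28 and 54 µg no gene passed in limma (smallest adjusted p 0.105, n = 4 against 5), with 1031 genes at an unadjusted p under 0.05, where 1202 would fall by chance. Glucocorticoid targets, genes induced by steroid hormones, had a median of 0.48 on 4 of 4 slides with 5 of 17 higher adjusted over the list alone (adjusted p = 6.43e-06, and 0.263 with an estimated correlation). CC chemokines had a median of -0.16 on 4 of 4 slides with 2 lower adjusted over the list alone (adjusted p = 0.00182, and 0.526 with an estimated correlation). Camera passed 13 lists, and none passed with an estimated correlation or by fry. The gene count was 0 with slide as a block, 20 (13 higher and 7 lower) with the compared groups alone, 51 with array weights and 16 without the 7 arrays of high muscle score, none of which belongs to day 28. It was 5 without replicate 1 of 54 µg, and the CC chemokine median was -0.27 without replicate 4 of 54 µg.

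The effect of each dose was then compared between the days. At 18 µg, 14 genes differed, 11 with a more positive and 3 with a more negative effect at day 28, against 2386 at an unadjusted p under 0.05. Gfpt2, an enzyme of hexosamine synthesis, had a difference of log2 1.57 (SE 0.25, n = 5 per group, adjusted p = 0.00294), from -0.81 at day 1 to 0.76 at day 28. Wdr92 differed by 1.54 (SE 0.23, adjusted p = 0.00133), Mst1r, a receptor kinase, by 1.23 (adjusted p = 0.0487), Mbd1 by 1.00 (adjusted p = 0.0487) and Timeless, a replication fork protein, by -0.70 (adjusted p = 0.0487), each in the same direction on 5 of 5 slides. Skeletal muscle markers differed by 3.91 in median (16 of 20 adjusted over the list alone, adjusted p = 4.58e-17, and 0.346 with an estimated correlation), beside high values in the day 1 controls, and were among 18 lists that passed camera, none with an estimated correlation or by fry. Gfpt2 (adjusted p = 0.0624), Mst1r (0.394) and Timeless (0.421) were not called with the muscle score as a covariate. Mst1r kept its call only without day 1 control replicate 1 or 3, replicate 1 or 3 of day 1 and 162 µg, replicate 4 of day 1 and 18 µg, replicate 2 or 5 of day 1 and 54 µg, day 28 control replicate 5, or replicate 1 of day 28 and 18 µg or 54 µg (adjusted p up to 0.125 otherwise). Mbd1 lost its call without 26 of the 38 arrays (up to 0.136), among them replicates 1, 3 and 5 of day 28 and 18 µg. Timeless lost its call without 35 (up to 0.123), keeping it only without day 1 control replicate 1, replicate 5 of day 1 and 54 µg or replicate 5 of day 28 and 18 µg. The count was 20 with slide as a block, 0 with median centring and 461 with array weights. It was 137 without day 1 control replicate 1. It was 10 to 20 without day 1 control replicate 3, replicate 1 or 3 of day 1 and 162 µg, replicate 4 of day 1 and 18 µg, replicate 2 or 5 of day 1 and 54 µg or replicate 2, 4 or 5 of day 28 and 18 µg. Without any other array it was 6 to 9.

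At 54 µg and 162 µg the difference between days was not called for any gene in limma, with 1084 and 2637 genes at an unadjusted p under 0.05. The counts were 0 and 2 with slide as a block and 0 and 811 with array weights. Saa3 had a difference of log2 -2.54 at 162 µg (adjusted p = 0.312), Cxcl5 of -2.53 (adjusted p = 0.23), Saa1 of -2.18 (adjusted p = 0.171) and Lcn2 of -1.57 (adjusted p = 0.111). At 54 µg goblet cells differed by -1.38 in median (1 lower adjusted over the list alone, 3 of 4 slides, adjusted p = 5.56e-09, and 0.274 with an estimated correlation) and CC chemokines by -0.32 (4 lower, 4 of 4 slides, adjusted p = 2.51e-06, and 0.138 with an estimated correlation), among 15 lists that passed camera, none with an estimated correlation or by fry. The goblet median was -0.79 without day 1 control replicate 1 and -0.75 without replicate 2 of day 28 and 54 µg. The count at 54 µg was 1 without day 28 control replicate 5. At 162 µg it was 67 and 2 without day 1 control replicates 1 and 3, 7 and 4 without replicates 3 and 5 of day 1 and 162 µg, and 2, 1 and 3 without replicates 1, 2 and 3 of day 1 and 54 µg. It was 2 without replicate 2 of day 28 and 162 µg, and 5, 2 and 3 without replicates 2, 3 and 5 of day 28 and 18 µg.

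As groups, 14 lists differed between days at 162 µg by camera and none with an estimated correlation. More negative at day 28 were acute phase proteins (median -0.38, 1 higher and 9 lower adjusted over the list alone, adjusted p = 6.37e-05), CXC chemokines (-0.29, 1 lower, 0.0453), and actin (-0.28, 2 lower, 1.37e-06). So were alveolar type 2 epithelium (-0.38, 3 lower, 3.16e-06), type 1 epithelium (-0.54, 1 lower, 9.09e-07) and endothelium (-0.35, 6.19e-06). Their adjusted p was 0.266 for the first 4 and 0.305 and 0.339 for the others with an estimated correlation. The unfolded protein response (-0.30, 1 higher and 7 lower, adjusted p = 5.89e-06, and 0.209 with an estimated correlation) also passed fry (0.0233). More positive were immediate early genes (0.29, 3 higher, adjusted p = 0.00903, and 0.577 with an estimated correlation), B cells (0.40, 0.000107, and an adjusted p = 0.511 with an estimated correlation) and eosinophils, mast cells and basophils (0.22, 4 higher, 0.00661, and an adjusted p = 0.266 with an estimated correlation). The neighbouring tissue lists moved with them, skeletal muscle by 3.08 (adjusted p = 1.73e-09, and 0.305 with an estimated correlation), and fat by 2.75 (8 higher, 9.97e-09, and an adjusted p = 0.304 with an estimated correlation). Cardiac muscle differed by 2.27 (1.61e-05, and an adjusted p = 0.577 with an estimated correlation) and upper airway by 1.35 (3 higher, 0.000537, and an adjusted p = 0.266 with an estimated correlation). The CXC call ended in 13 of the 38 fits without 1 array (0.0516 to 0.114) and with Agilent's signals, the series table, Cy5 alone, the filter of 19 arrays and array weights (0.0642 to 0.162). Placing the array of conflicting labels in day 1 ended the calls of CXC chemokines (0.245), immediate early genes (0.159) and eosinophils (0.0555). The covariate ended those of type 1 epithelium (median -0.045, adjusted p = 0.302), upper airway (0.81, 0.0590) and cardiac and skeletal muscle (-0.13 and 0.070, 0.505 and 0.980). The immediate early call ended without day 1 control replicate 1 (0.151) or 3 (0.0619) or replicate 3 of day 28 and 162 µg (0.0834). Among day 28 arrays of 162 µg, the acute phase median was -0.22 without replicate 1, type 2 epithelium -0.25 without replicate 4, CXC chemokines -0.44 without replicate 2, and eosinophils 0.33 and 0.14 without replicates 1 and 2. The acute phase median was -0.23 without day 28 control replicate 2 and that of B cells 0.26 without day 1 control replicate 2.

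The control groups of the 2 days differed in 22 genes, 9 higher and 13 lower at day 28, against 3031 at an unadjusted p under 0.05. Rasl11a, a small GTPase of the Ras family, was 2.24-fold higher at day 28 (log2 1.16, SE 0.18, n = 5 against 5, adjusted p = 0.00474). Phlda1 (log2 0.93, adjusted p = 0.0258), the adhesion molecule Vcam1 (log2 0.64, adjusted p = 0.0258), the kinase Pkn3 (log2 0.64, adjusted p = 0.0241) and the leukocyte sialophorin Spn (log2 0.56, adjusted p = 0.0494) were higher as well. The muscle genes Mybpc2 (log2 -2.99, 7.96-fold, adjusted p = 0.0494) and Cacng1 (log2 -2.13, at least 4.37-fold, adjusted p = 0.0494) and the cortexin gene Ctxn3 (log2 -1.98, at least 3.57-fold, adjusted p = 0.0499) were lower, all 8 genes in the same direction on 5 of 5 slides. Skeletal muscle markers were lower by a median of -3.78 (18 of 20 adjusted over the list alone, adjusted p = 2.06e-22, and 0.156 with an estimated correlation). Circadian clock genes were lower (median -0.34, 1 higher and 7 lower adjusted over the list alone, 4 of 5 slides, adjusted p = 1.48e-05, and 0.0912 with an estimated correlation), with a median of -0.19 without day 1 control replicate 1. The mean of the clock output gene Dbp was 1.62 ± 0.99 (SD, n = 5) at day 1 and 0.24 ± 0.92 (SD, n = 5) at day 28. Glucocorticoid targets were lower (median -0.49, 2 lower, adjusted p = 2.44e-05, and 0.184 with an estimated correlation) and interferon-stimulated genes higher (median 0.27, adjusted p = 9.38e-09, and 0.41 with an estimated correlation). In all 17 of 43 lists passed camera, 9 higher and 8 lower, 0 with an estimated correlation and 4 by fry.

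With the muscle score as a covariate 13 genes were called, of which 1, Rasl11a (adjusted p = 0.000885), was among the 22. The count was 289 (54 higher and 235 lower) with slide as a block, 0 with median centring, 0 with the compared groups alone, and 1545 with array weights. Every array left out moved it by more than 1.5 times. It was 1002, 254 and 491 without day 1 control replicates 1, 2 and 3, 308 and 42 without replicates 5 and 2 of day 1 and 54 µg, 47 without replicate 1 of day 1 and 162 µg, and 1 to 12 without any other array. Phlda1 lost its call without day 1 control replicate 5 or day 28 control replicate 2, 3, 4 or 5, and Vcam1 without day 1 control replicate 4 or 5 or day 28 control replicate 1, 3, 4 or 5 (both up to 0.218). Pkn3 lost it without day 1 control replicate 5 or day 28 control replicate 1, 3 or 4 (up to 0.162). Spn, Cacng1 and Ctxn3 kept theirs only without day 1 control replicate 1, 2 or 3, replicate 1 of day 1 and 162 µg or replicate 2 or 5 of day 1 and 54 µg, and Mybpc2 without these or replicate 1 of 54 µg (up to 0.247 otherwise).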

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

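The tests of muscle tissue, of another tissue, of a dose effect on muscle transcripts, all tests on the acute phase list and the muscle test of the circadian list were chosen only after the result was seen, while the time of day test and the counts over other splits of the arrays were planned before.

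Of 112 groups of arrays tested for a single array far from its group, 11 had one, where chance gives about 1 in 20 groups. At day 28, control replicate 1 had 43.2% of probes well above background (other arrays 50.8 to 53.5), and control replicate 2 had Saa3 at -2.68 (others -3.51 to -3.46). At day 28 and 162 µg, Cxcl5 was -0.95 in replicate 2 (others -2.89 to -2.57), Cd5l 1.47 in replicate 3 (others 0.31 to 0.44) and Sftpc 5.76 in replicate 4 (others 7.12 to 7.38). Replicate 4 of that group is the array with conflicting day labels. At day 28 and 54 µg, Cd5l was 0.58 in replicate 4 (others 0.28 to 0.29). At day 1 and 18 µg, replicate 5 had a liver score of 4.17 (others 0.35 to 0.43) and Cxcl5 at -3.20 (others -4.10 to -3.91). At day 1 and 54 µg, Slc26a4 was 1.74 in replicate 1 (others 3.94 to 4.54). At day 1 and 162 µg, replicate 1 had a skeletal muscle score of 4.09 (others -0.51 to 0.04) and Dbp at 1.12 (others 2.12 to 2.29).

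Effects that differed between days by the test of the difference itself were those of Gfpt2 (1.57), Wdr92 (1.54), Mst1r (1.23), Mbd1 (1.00) and Timeless (-0.70) at 18 µg, with 18 lists by camera, among them skeletal muscle (3.91). At 54 µg they were 15 lists by camera, among them CC chemokines (-0.32) and goblet cells (-1.38). At 162 µg they were the lists of acute phase proteins (-0.38), CXC chemokines (-0.29), actin (-0.28), the unfolded protein response (-0.30), immediate early genes (0.29), B cells (0.40), eosinophils, mast cells and basophils (0.22), alveolar type 2 epithelium (-0.38), type 1 epithelium (-0.54), endothelium (-0.35), cardiac muscle (2.27), skeletal muscle (3.08), fat (2.75) and upper airway (1.35). None of these lists passed with an estimated correlation.

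Skeletal muscle markers were high on 7 of the 20 day 1 arrays, from 3.59 to 5.56. Arrays of another tissue in place of lung are argued against by alveolar type 2 scores, since the lowest of the picked arrays was 0.18 above the lowest of the others. A dose of particles lowering muscle transcripts is argued against by arrays of a single dose lying more than 3 log2 apart in 3 of the 4 day 1 groups. Skeletal muscle tissue in the lung section remains a candidate explanation, as at least a share of 0.8 of the markers not used to pick the arrays lay more than 1 log2 above the other arrays. It was found and tested on the same data.

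The acute phase list was higher at day 1 and 162 µg. Neighbouring tissue in the controls as the whole cause is argued against by a median of 0.53 for 162 against 18 µg, where the 18 µg group is low in muscle markers. Liver tissue in the 162 µg sections is argued against by the liver list, with a median of -0.16. A dose of particles may underlie the pattern, as the median at 54 µg, 0.27, lies between -0.02 at 18 µg and 0.62 at 162 µg, and this stays a hypothesis.

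The circadian clock list was lower in day 28 than in day 1 controls, though not past the threshold with an estimated correlation (adjusted p = 0.0912). Skeletal muscle in the day 1 control sections is argued against by a median of -0.52 with the muscle score as a covariate. Time of day of collection cannot be told apart from other causes, because transcripts with an evening peak had a median of -0.42 while the 4 with a morning peak had one of 0.074, of which 2 were higher and 2 lower. The medians were -0.92 and 0.25 with the muscle score as a covariate, the directions that a difference in time of day predicts, so this explanation stays open. Age of the mice and time since instillation, which the design ties to the day, were not tested and stay open.

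For each count of called genes 100 random splits of the arrays were drawn, from 126 for a comparison of groups and 15876 for a difference between days. Chance can be excluded for 162 µg at day 1 (150 genes, highest other split 475, 2 splits as large), 18 µg at day 28 (20 genes, highest other 3, 1 split as large), the difference at 18 µg (14 genes, highest other 0, 1 split as large) and the controls (22 genes, highest other 503, 3 splits as large). It cannot be excluded for the count of 18 µg at day 1 without slide (1 gene, highest other 384, 8 splits as large). The splits were not drawn within slides, and slide as a block calls 437 genes there. For counts of 0 by limma all 100 splits are as large, with highest others of 3111 for 54 µg at day 1, 0 for 54 µg and 0 for 162 µg at day 28, and 1440 and 247 for the differences at 54 and 162 µg. Genes at an unadjusted p under 0.05 in these numbered 2201, 1031, 1637, 1084 and 2637, and slide as a block called 4, 0, 0, 0 and 2. Splits that call several times the real number point to a structure of the samples.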

How the results depend on the processing

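The muscle covariate alone or with slide as a block, the fit without the 7 arrays of high muscle score and 162 against 18 µg were chosen only after the result was seen, and the other settings were planned.

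The counts of called genes are given in the order 18, 54 and 162 µg at day 1, the same doses at day 28, their differences between days, and the controls. Where a setting is not named for a count, that count stayed within 1.5 times its value in the report. Without background correction the differences at 18 and 162 µg gave 6 and 1 and the controls 10. Agilent's processed signals gave 6 at 18 µg of day 1, 3 at 162 µg of day 28 and 1 for the difference at 162 µg. Median centring gave 19 at 162 µg of day 1, and 0 at 18 µg of day 28, for the difference at 18 µg and for the controls. Scale normalization gave 16 at 18 µg of day 1, 8 and 1 for the differences at 18 and 162 µg, and 47 for the controls. The series table gave 1 at 54 µg of day 1 and 7 and 1 for the differences at 18 and 162 µg. Cy5 alone gave 2 at 18 µg of day 1, 13 at 18 µg of day 28 and 3 for the difference at 162 µg. No filter gave 6 and 1 for the differences at 18 and 162 µg and 9 for the controls. The filter of 19 arrays gave 7 for the controls. The mean of probes gave 5 for the difference at 18 µg and 7 for the controls. Trend and robust gave 6 and 8 for the same results. Slide as a fixed block gave 437, 4 and 349 at day 1, 45 at 18 µg of day 28, 2 for the difference at 162 µg and 289 for the controls. Slide as a random block (correlation 0.102) gave 362, 290, 52, 23, 2 and 287 for 18 and 162 µg of day 1, 18 µg of day 28, the differences at 18 and 162 µg, and the controls. The compared groups alone gave 12 at 162 µg of day 1, 7, 20 and 2 at day 28, 9 for the difference at 18 µg and 0 for the controls. Array weights gave 2100, 385 and 1705 at day 1, 31 and 51 at 18 and 54 µg of day 28, 461 and 811 for the differences at 18 and 162 µg, and 1545 for the controls. Leaving out the array with conflicting labels gave 7 at 18 µg of day 1, 6 for the difference at 18 µg and 8 for the controls. Placing it in day 1 gave 0 at 18 µg and 94 at 162 µg of day 1, 6 for the difference at 18 µg and 9 for the controls. The 1.5-fold minimum moved no count beyond that range. The cause of these shifts was not tested, except that filters and left-out arrays change how many genes or arrays are tested.

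With the muscle score as a covariate the counts were 3, 259 and 23 at day 1, 53 at 18 µg of day 28 and 13 for the controls. With the score and slide as a block they were 3, 249 and 28 at day 1, 127 and 7 at 18 and 54 µg of day 28, 5 for the difference at 162 µg and 7 for the controls. Without the 7 arrays they were 2 and 1 at 54 and 162 µg of day 1, 60 and 16 at day 28, and 6, 1 and 1 for the differences. This leaves 1 day 1 control, which is assumed to vary like the other groups. For 162 against 18 µg there were 13.

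Leaving out 1 array at a time gave 0 to 1697, 0 to 251 and 30 to 1337 genes at day 1, 15 to 52, 0 to 5 and 0 to 3 at day 28, 6 to 137, 0 to 1 and 0 to 67 for the differences, and 1 to 1002 for the controls. The extremes were reached without day 1 control replicate 1 (1697, 1337, 137, 67 and 1002), 2 (251), 4 (0) or 5 (30 and 1), day 28 and 18 µg replicate 2 (15) or 4 (52), day 28 and 54 µg replicate 1 (5), day 28 and 162 µg replicate 1 (3) and day 28 control replicate 5 (1).

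Some genes, and the direction of some list tests, reversed, and the cause was not tested. The median kept its sign for complement with the covariate and skeletal muscle at day 1 and 18 µg, and, for the difference at 162 µg, for eosinophils and for cardiac and skeletal muscle with covariate and slide. A result not past the threshold counts here only where a setting called it the other way. At day 1 and 162 µg the muscle covariate gave complement -0.043, type 1 epithelium -0.16, endothelium -0.039 and cardiac muscle 0.40. With slide as a block as well, the last 3 were -0.13, -0.047 and 0.24. Without the 7 arrays complement was 0.10, T cells -0.041, type 1 epithelium -0.013, fibroblasts 0.087 and cardiac muscle 0.53. Fat was 0.37, upper airway 0.10, erythroid cells 0.16, Chrna9 0.062 and F13a1 0.14. For 162 against 18 µg complement was 0.025, T cells -0.083, type 1 epithelium -0.12, endothelium -0.030, mesothelium 0.077 and cardiac muscle 1.32. Skeletal muscle was 0.95, fat 0.46, upper airway 0.054, Chrna9 0.025, Krt14 0.042 and Alox15 0.048. At day 28 and 162 µg actin was 0.14 with median centring, club cells 0.0078 in Cy5 alone and ciliated cells -0.11 with Agilent's signals. At day 1 and 18 µg the covariate gave skeletal muscle -0.017 (-0.072 with slide as a block) and actin -0.035. The circadian list was -0.053 without the 7 arrays. For the difference at 162 µg, cardiac muscle was -0.13 with the covariate, 0.12 with slide as well and -0.037 without the 7 arrays. Eosinophils were 0.058 and upper airway -0.10 without them, and skeletal muscle was 0.068 with covariate and slide. In the controls skeletal muscle was 0.077 without the 7 arrays.

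Under the planned settings, list results at day 1 and 162 µg were the same in 1141 cases and weaker in 91, and at day 28 the same in 1039, weaker in 134 and reversed in 3. Named genes at day 1 and 162 µg kept their status, mostly uncalled whatever the value, in 6576 cases, gained a call in 230 and lost it in 227. The between-array Aquantile step changed no log2 ratio and so tests nothing. Slide as a random block was run without the lists, and Krt4 has no value without the 7 arrays. Signal over background limits the folds of dim genes such as Saa2 and Chrna9, which are lower bounds, and 43.2% to 56.2% of probes were well above it.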
